A study of Homo sapiens with 32 samples.

How the data were processed

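The deposited table held counts of reads per gene for 32 libraries and 60728 Ensembl genes, all of them whole numbers. Per the submitters' processing notes, the authors aligned the reads with STAR 2.7.10a to GRCh38.p13 and made the counts with featureCounts. The notes give neither the annotation release nor how strand and reads with several matches were treated. Per the labels' protocols, libraries were made with a stranded kit for polyadenylated RNA. Gene symbols were found by gene ID for 60370 genes in a table of gene names, and for 60659 with the names of GENCODE 29 added. Where a symbol had several IDs, the ID with the highest total count stood for it. Positions, gene types and transcript lengths came from GENCODE 29 on GRCh38. HLA-B, ribosomal protein genes with their pseudogenes, and genes that overlap another can hold reads of near-identical or overlapping genes, so their values are less certain. Values of some named genes are not reported here.

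All comparisons, lists, rules and the first set of alternatives were chosen before the data were examined. In A549 each group had libraries titled 1, 2, 2-2 and 3, and the labels number both 2 and 2-2 as replicate 2, so their counts were added. Measured by the SD of log2 ratios between libraries of a group, 2-2 lay closest to 3 (0.219 to 0.269 over the 4 groups), while 2 and 2-2 differed by 0.537 to 0.673 and 1 and 3 by 0.502 to 0.75. Fits with both apart or either alone are among the alternatives. As 2 holds 2-2, replicates 2 and 3 may be dependent, so A549's n and p-values are in doubt. The labels do not say whether replicates were separate cultures, and p-values measure only the spread between the samples.

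Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group and quasi-likelihood F tests, using all 4 groups of a line and no block. Tests were 2-sided. Each line was fitted on its own, and differences between the lines were tested as interactions over all 8 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Adjusted p-values given for genes come from this test. The standard error of a log2 fold change was the fold change divided by the root of F. Counts-per-million (CPM) of genes use TMM-scaled totals, given as mean and SD over replicates. Genes without a count in 1 group are given as a bound against a floor of 3 counts over the group, and genes with 1 to 3 counts as a ratio with a 95% counting interval. List medians with such genes at their bound were the same to 2 decimals in every list and comparison.

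The 17 gene lists tested were proliferation, p53 targets, the senescence-associated secretory genes, interferon-stimulated genes, MHC class I presentation, lysosome, cholesterol, serine and one-carbon metabolism, ATF4 targets, ribosome biogenesis, ribosomal proteins, FOXO targets, heterochromatin and lamina, the BCL2 family, glycolysis and hypoxia, the respiratory chain, and the melanocyte lineage, the last in SK-MEL-147 alone. Adjusted p-values given for lists come from fry of limma 3.58.1 on the edgeR fit, adjusted over the lists of a comparison. This test asks whether the genes of a list move, on balance, one way. It does not compare them with other genes. Epithelial, leukocyte and fibroblast lists and the mitochondrial mRNAs were read as levels. Genes to be named were, per comparison, the 5 largest rises and the 5 largest falls among called protein-coding genes with at least 10 CPM on average in the higher group and replicates that did not overlap. To these came a panel of 12 genes in comparisons with control, and up to 2 called members per list and direction.

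Simulated counts with 200 genes changed, far fewer than the data's calls, were tested first, so their rates do not carry over. For doxorubicin against control in A549 (19533 genes) edgeR recovered 2.99%, 34.3% and 86.4% at 1.5, 2 and 4-fold, and 5.05% of its calls were false. In SK-MEL-147 (18511 genes) it recovered 14.9%, 67.2% and 86.4%, with 3.65% false. DESeq2 1.42.0, used as an alternative, had 19.9% and 12.4% false calls. A moved list of 30 genes had fry p 1.3e-07 and 7.51e-14 in the same order, and an unchanged one 0.287 and 0.525.

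Whether replicate numbers pair the samples was read from the data, as the correlation of deviations from the group means between samples with the same number. Pairs were taken where every correlation was above 0.1. In A549 the correlations ran from 0.17 to 0.648 over the 5 comparisons, so that its numbers paired the samples. In SK-MEL-147 this held for INK128 against control (0.214 to 0.288) and against doxorubicin (0.309 to 0.553), and not for the other 3 comparisons. The main fits leave these pairs out. A fit with the replicate block is given beside a result whose call it changed, or else among the alternatives. Shares of counts were compared by exact permutation tests with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.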

Results

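Polyadenylated RNA was sequenced from 2 human tumour cell lines, A549 (lung adenocarcinoma) and SK-MEL-147 (melanoma), collected on day 7 of treatment with 1 of 3 drugs or of no treatment. Doxorubicin, which poisons topoisomerase and breaks DNA, was given at 100 nM to both lines. Palbociclib, an inhibitor of the cyclin D-dependent kinases, was given at 5 uM to A549 and at 1 uM to SK-MEL-147. INK128, an ATP-competitive inhibitor of the growth kinase mTOR, was given at 200 nM to A549 and at 100 nM to SK-MEL-147. The first 2 drugs were withdrawn after 72 h, while INK128 was renewed with the medium every 3 days. By the labels, doxorubicin and palbociclib put the cells into senescence, a lasting arrest of the cell cycle, and INK128 put them into a state like diapause, the reversible dormancy of early embryos. The 8 groups held 4 libraries each, 32 in all, with 28150560 to 33331334 counts a library in A549 and 17929732 to 32407057 in SK-MEL-147. With the libraries numbered 2 added, n was 3 per group in A549 (in doubt, see above) and 4 in SK-MEL-147. The series description names another melanoma line for the INK128 treatment, and every sample label names SK-MEL-147, which was followed here.

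Each line had higher sums of its origin's genes in every group. In untreated cells 20 epithelial genes summed to 10490 counts-per-million (CPM) in A549, with libraries from 8424 to 12020, and to 182 CPM in SK-MEL-147. The 17 melanocyte genes, some too weak to test, summed to 397 CPM in SK-MEL-147 and 32.2 CPM in A549, also untreated. The 12 leukocyte genes summed to 3.29 to 15.9 CPM over the 8 group means. The 10 fibroblast genes stood at 20.6, 103, 134 and 15.3 CPM in SK-MEL-147 without treatment and with doxorubicin, palbociclib and INK128, and at 13.4, 37.6, 31.1 and 10.6 CPM in A549 in the same order. With INK128 the epithelial sum in A549 was 4709 CPM and the melanocyte sum in SK-MEL-147 682 CPM, though that list did not pass. Transcripts of the mitochondrial genome made up 7.7% ± 0.518 of the counts in untreated A549 (SD, n = 3), 12% ± 5.44 with doxorubicin, 12% ± 4.62 with palbociclib and 13.2% ± 1.08 with INK128. In SK-MEL-147 they made up 2.72% ± 0.398, 4.42% ± 0.907, 5.26% ± 0.463 and 3.7% ± 0.907 in the same order (SD, n = 4). By 2-sided exact permutation tests of this share against control, p was 0.1 for each drug in A549, the smallest that 3 samples against 3 allow, and 0.0286, 0.0286 and 0.0571 in SK-MEL-147; after Benjamini-Hochberg adjustment over 18 shares tested, none of the 6 passed (adjusted p 0.0858 to 0.138). Pseudogenes of the nuclear genome made up 7.34% ± 0.183, 7.19% ± 1.11, 7.78% ± 0.909 and 10.1% ± 0.809 in A549, in the same order, and 8.29% ± 0.449, 6.61% ± 0.53, 6.58% ± 0.399 and 10.4% ± 0.683 in SK-MEL-147. Protein-coding genes of the nuclear genome made up 83.9% ± 0.656, 79.8% ± 6.58, 79.3% ± 5.57 and 75.4% ± 1.89 in A549 and 87.8% ± 0.225, 87.8% ± 1.14, 87% ± 0.71 and 84.3% ± 1.71 in SK-MEL-147. With INK128 each of these 2 shares had exact permutation p 0.1 in A549 and 0.0286 in SK-MEL-147 (adjusted p 0.138 and 0.0858).

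Of 12 genes set out in advance as a panel, 5 mark the cell cycle and its arrest: CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), a gene of cycling cells, LMNB1 (ENSG00000113368, chromosome 5, 126776623 to 126837020), which encodes lamin B of the nuclear envelope, GLB1 (ENSG00000170266, chromosome 3, 32996608 to 33097230), the lysosomal galactosidase behind the common stain for senescence, and GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a stress cytokine. The others were the secreted factors IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) and CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), the MHC class I light chain B2M (ENSG00000166710, chromosome 15, 44711487 to 44718877), the survival gene BCL2L1 (ENSG00000171552, chromosome 20, 31664452 to 31723989), the histone methyltransferase genes KMT5B (ENSG00000110066, chromosome 11, 68154863 to 68213828) and KMT5C (ENSG00000133247, chromosome 19, 55339853 to 55348120), and SHMT2 (ENSG00000182199, chromosome 12, 57229327 to 57234935), the mitochondrial serine hydroxymethyltransferase. Positions are on GRCh38.

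**Figure D1:**
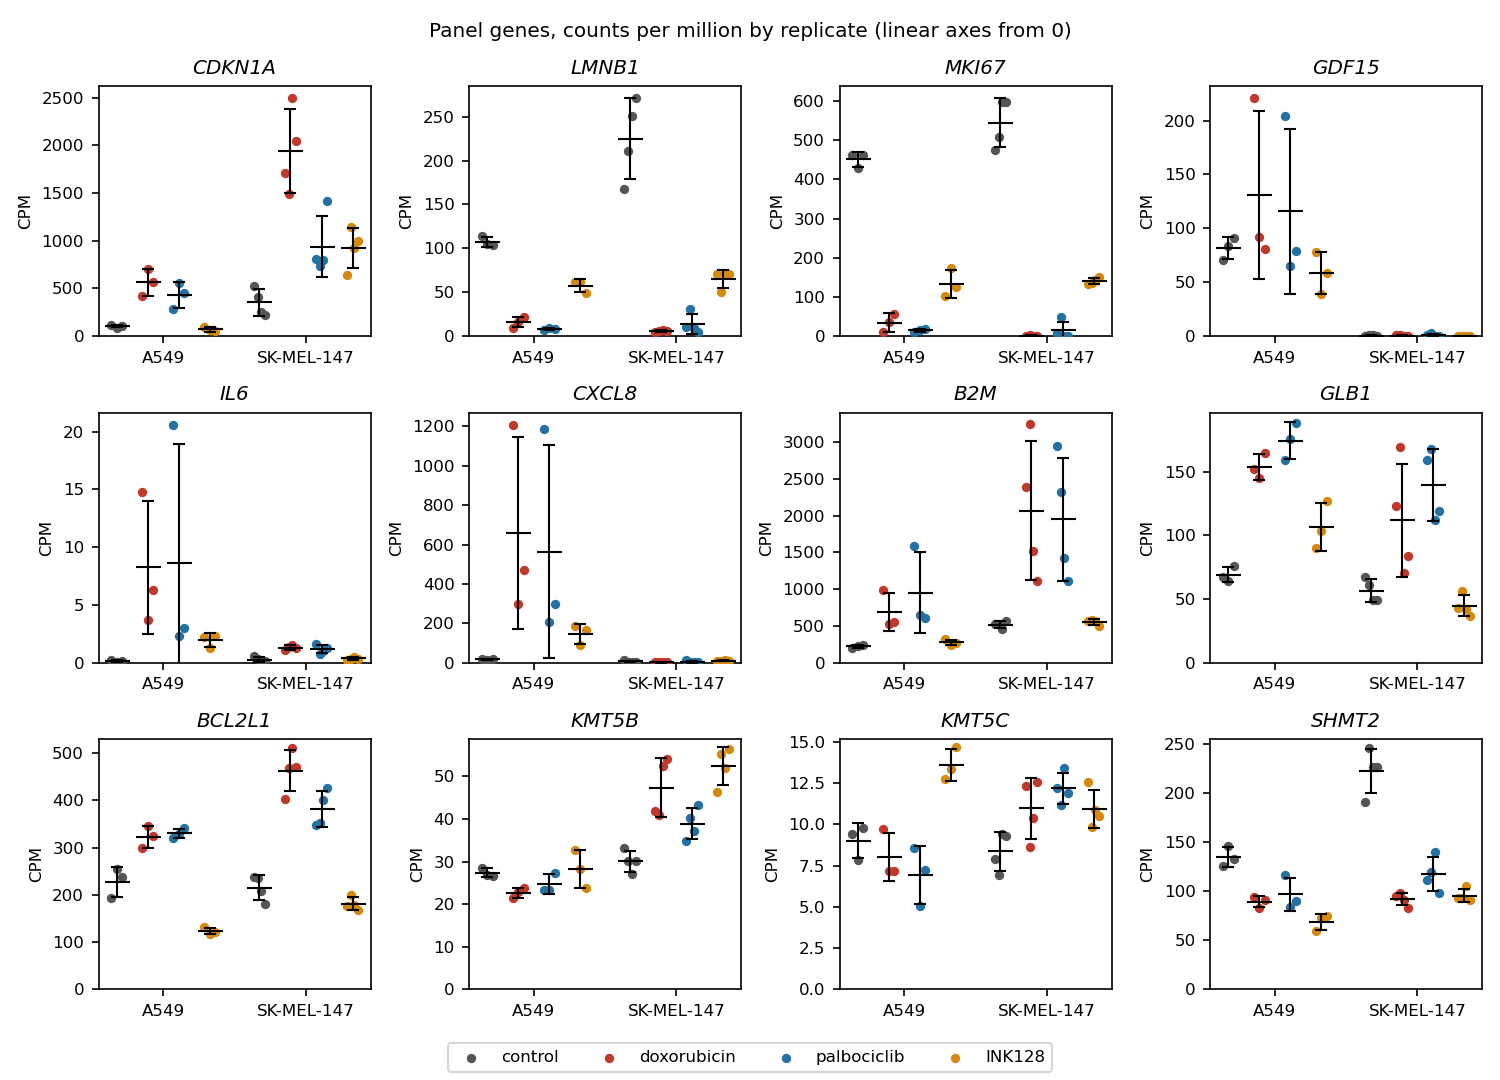
Counts-per-million of the 12 panel genes on linear axes from 0, by cell line and treatment (colour), where points are replicates (n = 3 in A549, n = 4 in SK-MEL-147) and black marks give group means with SD. CDKN1A stood at 562 CPM with doxorubicin, 429 with palbociclib and 69.1 with INK128 in A549, against 102 in control cells.

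Doxorubicin in A549 was compared with no treatment to ask how the DNA-damaged, senescent cells differed. All 32 of the 32 proliferation genes fell (median -3.03, adjusted p 3.92e-06). Here and below, counts of list members follow the adjustment over all genes tested, and the counts higher and lower adjusted over the list alone are added where they differed. With INK128 against the inducers, 0 were called in a direction not given. The cell cycle transcription factor gene FOXM1 fell by 3.81 ± 0.37 on the log2 scale (standard error, n = 3 against 3 throughout A549). MKI67 fell by 3.73 ± 0.51, and the replication gene MCM10, among the 5 largest falls, was at -4.05 ± 0.4. Heterochromatin and lamina genes were lower in 16 of 26 cases and higher in 0 (median -0.74, adjusted p 3.92e-06). Of these, LMNB1 fell from 107 ± 5.45 to 15.7 ± 5.91 CPM (adjusted p 8.54e-06) and UHRF1, which keeps DNA methylation through replication, fell by 2.86 ± 0.23. Targets of p53 rose (19 of 25 higher, 0 lower, median 1.17, adjusted p 0.000192). CDKN1A stood at 562 ± 140 CPM against 102 ± 12 CPM (2.47 ± 0.29, adjusted p 6.6e-05), and TP53INP1, a p53-induced stress gene, rose by 3.17 ± 0.32. Targets of the FOXO transcription factors also rose (17 of 21 higher, 1 lower, median 1.32, adjusted p 3.92e-06), with PIK3IP1, an inhibitor of PI3 kinase signalling, at 3.79 ± 0.5.

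Inflammatory and interferon genes were higher in A549 with doxorubicin. Of the 35 secretory genes linked to senescence, 22 were higher and 3 lower (24 and 3 over the list alone, median 2.19, adjusted p 0.000734). The neutrophil chemokine CXCL8 stood at 658 ± 486 CPM against 16.8 ± 3.09 CPM (5.3 ± 0.76, adjusted p 0.000217). The growth factor genes AREG (-1.78 ± 0.22) and EREG (-1.49 ± 0.2) fell. Interferon-stimulated genes rose in 34 of 39 cases and fell in 0 (35 and 0 over the list alone, median 3.33, adjusted p 0.0055), and IFI44 rose by 7.18 ± 1.68. RSAD2, which encodes the antiviral enzyme viperin, had no count in control libraries and was at least 56.6-fold higher against a floor of 3 counts over the group. Genes of MHC class I antigen presentation rose in 11 of 17 cases (12 and 0 over the list alone, median 1.5, adjusted p 0.00226). HLA-B went from 25.9 to 129 CPM and B2M from 219.9 to 690.5 CPM (adjusted p 0.00313 and 0.00314). Doxorubicin replicate 1 stood apart in these groups. Its interferon-stimulated genes summed to 1893 CPM, against 1140 to 1147 in the other 2 replicates and 513 to 615 in controls. The mitochondrial genome gave 18.3% of its counts (95% Wilson interval 18.29 to 18.32%, for counting error only), against 7.53 to 9.38% in the other 3 libraries. Without it the log2 fold change was 4.53 for CXCL8 and 5.49 for IFI44.

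Metabolic and biosynthetic genes moved in A549 with doxorubicin as well. Lysosomal genes rose (27 of 40 higher, 3 lower, median 0.68, adjusted p 0.00111). The fucosidase gene FUCA1 rose by 1.64 ± 0.14, GLB1 rose by 1.16 ± 0.14, and PSAP, the precursor of the saposins, stood at 2891 ± 204 CPM against 1034 ± 96.1 CPM. Ribosome biogenesis genes fell (0 of 30 higher, 28 lower, 0 and 29 over the list alone, median -1.03, adjusted p 1.59e-07), and BOP1, a factor of the large ribosomal subunit, fell by 1.68 ± 0.19. Genes of serine and one-carbon metabolism fell (1 of 26 higher, 15 lower, 1 and 16 over the list alone, median -0.57, adjusted p 9.33e-06). Cholesterol genes fell (1 of 23 higher, 11 lower, 1 and 14 over the list alone, median -0.76, adjusted p 0.00754). Glycolysis and hypoxia genes went both ways (8 of 28 higher, 4 lower, median 0.42, adjusted p 0.0139). The lactate exporter gene SLC16A3 rose by 2.16 ± 0.28 and the enolase gene ENO1 fell by 0.62 ± 0.13. ATF4 targets, a stress response list, were higher in 3 and lower in 7 of 24 cases (median -0.22, adjusted p 0.0204), and the amino acid transporter gene SLC7A5 fell by 1.5 ± 0.22. Of the BCL2 family, 5 of 16 were higher and 1 lower (5 and 2 over the list alone, median 0.34, adjusted p 0.0154), with the pro-apoptotic genes BMF (2.45 ± 0.38) and BBC3 (1.8 ± 0.25) up. Neither ribosomal protein genes (0 of 53 higher, 6 lower, 0 and 2 over the list alone, median -0.23, adjusted p 0.158) nor nuclear genes of the respiratory chain (1 of 36 higher, 5 lower, 1 and 4 over the list alone, median 0.01, adjusted p 0.648) passed. In all, 4381 genes were higher and 4082 lower of 19550 tested, 2744 and 1562 of them by more than 1 on the log2 scale (edgeR quasi-likelihood test). The ATF4 call was lost without control replicate 1 or doxorubicin replicate 1 or 3 (adjusted p 0.0511 to 0.106) and with both A549 libraries numbered 2 kept apart (0.152, range over alternatives 0.0127 to 0.152), and the BCL2 family call without doxorubicin replicate 1 or control replicate 3 (0.0541 to 0.073). The cholesterol list had adjusted p 0.052 without replicate 1 of every A549 group, an alternative chosen after seeing the data (range over alternatives 0.000446 to 0.052), and ribosomal protein genes had 0.0258 (median -0.41, range 0.0258 to 0.503). The glycolysis list had 0.0535 with scaling by library size alone (range 0.00113 to 0.0535).

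Palbociclib, which arrests the cycle without damaging DNA directly, was compared with no treatment in A549. All 32 of 32 proliferation genes fell (median -3.89, adjusted p 1.96e-05). MKI67 fell from 451 ± 18.2 to 14.5 ± 4.13 CPM (-4.96 ± 0.54, adjusted p 3.14e-05). The transcription factor genes E2F8 (-5.47 ± 0.41) and MYBL2 (-5.24 ± 0.43), which act in the S phase, were among the largest falls. LMNB1 fell by 3.77 ± 0.25, and 18 of 26 heterochromatin and lamina genes were lower and 0 higher (0 and 20 over the list alone, median -0.82, adjusted p 4.92e-06). Targets of p53 rose in 15 of 25 cases and fell in 2 (median 0.95, adjusted p 0.00105), CDKN1A by 2.08 ± 0.29, adjusted p 0.000181. FOXO targets rose in 18 of 21 (median 1.48, adjusted p 3.38e-06), and PIK3IP1 rose by 3.79 ± 0.5. Lysosomal genes rose (27 of 40 higher, 2 lower, 29 and 2 over the list alone, median 0.83, adjusted p 0.000215), among them GRN, which encodes progranulin, by 1.76 ± 0.17.

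The same inflammatory groups were higher with palbociclib in A549. Of the secretory genes 21 of 35 were higher and 3 lower (22 and 3 over the list alone, median 1.99, adjusted p 0.00105). CXCL8 rose by 5.07 ± 0.75 and AREG fell by 1.58 ± 0.21. Of the interferon-stimulated genes 37 of 39 were higher and 0 lower (median 4.74, adjusted p 0.00283). RSAD2 was at least 151-fold higher than in controls, where it had no count. MHC class I genes rose in 12 of 17 cases (15 and 0 over the list alone, median 1.62, adjusted p 0.00105), HLA-B to 238 ± 205 CPM against 25.9 ± 0.604 CPM. Palbociclib replicate 1 was far above the others in these groups. Its interferon-stimulated genes summed to 5166 CPM against 1353 to 1555 in the other 2 replicates. The mitochondrial genome gave 17.3% of its counts (95% Wilson interval 17.32 to 17.35%) against 8.3 to 9.81% in the other 3 libraries. Without it the median log2 fold change of the interferon list was 3.68, and single genes had 2.22 (HLA-B) and 3.92 (CXCL8).

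Genes of ribosome biogenesis and one-carbon metabolism fell with palbociclib in A549. Ribosome biogenesis genes were lower (0 of 30 higher, 28 lower, 0 and 30 over the list alone, median -0.96, adjusted p 2.86e-07), and BOP1 fell by 1.66 ± 0.19. Genes of serine and one-carbon metabolism fell (1 of 26 higher, 13 lower, 2 and 14 over the list alone, median -0.48, adjusted p 1.96e-05), with the nucleotide synthesis gene TYMS at -2.44 ± 0.26. Glycolysis and hypoxia genes were mixed (9 of 28 higher, 5 lower, 10 and 5 over the list alone, median 0.52, adjusted p 0.00978). SLC16A3 rose by 1.91 ± 0.28 and the phosphofructokinase gene PFKP fell by 0.84 ± 0.16. Of the BCL2 family 3 of 16 were higher and 2 lower (median 0.37, adjusted p 0.0351), with BMF and BBC3 up (2.03 ± 0.38 and 1.62 ± 0.25). Cholesterol genes (3 of 23 higher, 4 lower, median -0.17, adjusted p 0.373) and ATF4 targets (8 of 24 higher, 4 lower, median -0.03, adjusted p 0.373, mean 0.26) did not pass. Nor did ribosomal protein genes (0 of 53 higher, 0 lower, median 0.05, adjusted p 0.698) or respiratory chain genes (2 of 36 higher, 5 lower, 1 and 2 over the list alone, median -0.03, adjusted p 0.683). Over all genes, 4348 were higher and 4123 lower of 19550, 2685 and 1683 by more than 1 on the log2 scale. The BCL2 family call was lost without any one of the 3 controls or palbociclib replicate 1 (adjusted p 0.0509 to 0.143) and with scaling by library size alone (0.0604, range over alternatives 0.00504 to 0.143). The list of glycolysis and hypoxia had adjusted p 0.0735 with scaling by library size alone (range over alternatives 0.000848 to 0.0735).

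INK128 in A549 was compared with no treatment to ask what the mTOR inhibitor did in the state called diapause-like. Of the ribosomal protein genes 41 of 53 rose and 0 fell (50 and 0 over the list alone, median 0.76, adjusted p 0.00346). RPL12 rose from 448 ± 33.6 to 1178 ± 232 CPM (1.4 ± 0.24, adjusted p 0.0012). Ribosome biogenesis genes fell (0 of 30 higher, 15 lower, 0 and 17 over the list alone, median -0.54, adjusted p 1.6e-05), and the assembly factor gene BYSL fell by 1.11 ± 0.14. Proliferation genes fell in 28 of 32 cases with 0 higher (0 and 31 over the list alone, median -1.42, adjusted p 0.00388). The mitotic kinase gene AURKA had -2.65 ± 0.25, MKI67 -1.75 ± 0.47 and LMNB1 -0.91 ± 0.23. FOXO targets rose (14 of 21 higher, 2 lower, 16 and 2 over the list alone, median 0.98, adjusted p 2.52e-05), and the ubiquitin ligase gene FBXO32 rose by 3.16 ± 0.21. The BCL2 family went both ways (3 of 16 higher, 5 lower, median -0.09, adjusted p 0.808, mean 0.24). BMF, also driven by FOXO factors, rose by 4.13 ± 0.39, and BCL2L1 fell by 0.88 ± 0.12. The largest falls included genes of lining epithelia, UPK3B (-4.62 ± 0.2) and the keratin gene KRT4 (-5.52 ± 1.1).

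Genes of sterol, serine and sugar metabolism fell in A549 with INK128. Cholesterol genes fell (1 of 23 higher, 18 lower, 1 and 19 over the list alone, median -0.82, adjusted p 0.000457). The sterol carrier gene STARD4 fell by 2.8 ± 0.32. Genes of serine and one-carbon metabolism fell (0 of 26 higher, 16 lower, 0 and 17 over the list alone, median -0.65, adjusted p 1.48e-05). PSAT1 of serine synthesis fell from 273 to 58.8 CPM (adjusted p 7.39e-06) and SHMT2 fell by 0.98 ± 0.14. ATF4 targets fell (1 of 24 higher, 13 lower, 5 and 15 over the list alone, median -0.68, adjusted p 2.52e-05), with the stress gene NUPR1 at -3.77 ± 0.44. Genes of glycolysis and hypoxia fell (2 of 28 higher, 13 lower, median -0.29, adjusted p 0.00122), with the glycolytic mutase gene PGAM1 at -1.5 ± 0.14. Respiratory chain genes were lower in 14 of 36 cases (median -0.37, adjusted p 0.0191), such as the subunit gene UQCRFS1 (-0.93 ± 0.16). That call was lost without replicate 2 or 3 of either group (adjusted p 0.0508 to 0.0721). The mitochondrial genome's own transcripts had a higher mean share of counts in these libraries than in controls, as given above.

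Gene groups linked to senescence went different ways with INK128 in A549. Targets of p53 were lower in 12 of 25 cases and higher in 2 (2 and 13 over the list alone, median -0.49, adjusted p 0.0187). TIGAR, a p53-induced regulator of glycolysis, fell by 1.44 ± 0.28, and BBC3 rose by 1.34 ± 0.25. CDKN1A stood at 69.1 ± 22.3 CPM against 102 ± 12 CPM (-0.56 ± 0.28, adjusted p 0.134). Secretory genes were higher in 14 of 35 cases and lower in 2 (median 1.3, adjusted p 0.0191), CXCL8 by 3.13 ± 0.69 and ANGPTL4 by -1.24 ± 0.15. IL6 rose by 3.88 ± 1.08 (adjusted p 0.0143, and 0.0715 without control replicate 2) and GLB1 rose by 0.63 ± 0.14 (adjusted p 0.00416). Interferon-stimulated genes (4 of 39 higher, 4 lower, 3 and 1 over the list alone, median 0.47, adjusted p 0.534) and MHC class I genes (4 of 17 higher, 2 lower, median 0.16, adjusted p 0.603) showed no shift in common. The antiviral gene OAS1 fell by 2.59 ± 0.54 and the signalling gene STAT2 rose by 1.14 ± 0.22. Lysosomal genes were higher in 15 of 40 cases and lower in 5 (median 0.15, adjusted p 0.126). Genes of heterochromatin and the lamina fell on balance (4 of 26 higher, 12 lower, 4 and 15 over the list alone, median -0.4, adjusted p 0.00607). LMNB2 fell by 1.28 ± 0.29, while HMGA2, a chromatin gene of embryonic and tumour cells, rose by 1.35 ± 0.28. Over all genes, 4010 were higher and 3856 lower of 19550, 2238 and 1184 by more than 1 on the log2 scale. The p53 list had adjusted p 0.0646 to 0.0663 without INK128 replicate 2 or 3, and CDKN1A 0.0383 without INK128 replicate 1 and 0.0024 without replicate 1 of every group (range over alternatives 0.0024 to 0.343). The secretory call was lost without control replicate 2 or 3 or INK128 replicate 3 (adjusted p 0.059 to 0.0796) and with both A549 libraries numbered 2 kept apart (0.0914, range over alternatives 0.00295 to 0.0914), and the median was 0.63 without INK128 replicate 1. The lysosomal list had adjusted p 0.0324 with replicates as blocks (replicate block) and 0.0452 without INK128 replicate 1 (range over alternatives 0.0324 to 0.431).

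INK128 was set against each senescence inducer directly to separate the states in A549, with doxorubicin given first and palbociclib second. Interferon-stimulated genes were lower with INK128 in 29 and 34 of 39 (medians -2.53 and -3.74, adjusted p 0.0109 and 0.00384, 0 and 31 against the first and 0 and 38 against the second over the list alone). These medians were -1.77 and -2.98 without replicate 1 of the inducer, whose high mitochondrial share and interferon sums are given above. MHC class I genes were lower in 13 and 15 of 17 (medians -0.85 and -1.14, adjusted p 0.00513 and 0.0018, 0 and 16 against the second over the list alone). Targets of p53 were lower in 22 and 19 of 25 (medians -1.45 and -1.27, adjusted p 2.74e-05 and 6.18e-05, 0 and 23 against the first and 0 and 20 against the second over the list alone), and CDKN1A had -3.03 ± 0.3, adjusted p 4e-05 against doxorubicin. Secretory genes were lower in 14 and 14 of 35 (2 and 1 higher, medians -0.83 and -0.94, adjusted p 0.0129 and 0.0151, 2 and 15 against the first over the list alone). The binding protein gene IGFBP5 was lower (-3.63 ± 0.8 and -4.46 ± 0.82) and EREG higher (1.06 ± 0.2 and 1.06 ± 0.2).

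Proliferation and ribosome genes were higher with INK128 than with either inducer in A549. Proliferation genes were higher in 29 and 30 of 32 (medians 1.63 and 2.4, adjusted p 0.000456 and 0.000268, 31 and 0 against the second over the list alone). CDT1, which licenses replication origins, had 2.94 ± 0.3 and 3.99 ± 0.31. Ribosomal protein genes were higher in 50 and 38 of 53 (medians 0.98 and 0.68, adjusted p 0.000456 and 0.00341, 51 and 0 against the first and 45 and 0 against the second over the list alone). Ribosome biogenesis genes were higher in 17 and 15 of 30 (medians 0.5 and 0.41, adjusted p 2.74e-05 and 6.17e-05, 18 and 0 against the first and 17 and 0 against the second over the list alone), FBL by 1.48 ± 0.14 and 1.48 ± 0.14. Heterochromatin and lamina genes were higher in 14 and 15 of 26 (medians 0.53 and 0.63, adjusted p 9.92e-05 and 6.18e-05, 16 and 0 against the first and 17 and 0 against the second over the list alone), HMGA2 by 2.6 ± 0.29 and 2.81 ± 0.3. Lysosomal genes were lower in 19 and 21 of 40 (4 and 0 higher, medians -0.48 and -0.68, adjusted p 0.00991 and 0.000986), with the protease gene CTSB at -1.12 ± 0.2 and -1.42 ± 0.2. Genes of glycolysis and hypoxia were lower in 15 and 17 of 28 (medians -0.66 and -0.64, adjusted p 9.92e-05 and 6.18e-05, 0 and 16 against the first and 0 and 18 against the second over the list alone). Cholesterol genes were lower in 12 and 14 of 23 (medians -0.45 and -0.83, adjusted p 0.0167 and 0.00116, 0 and 15 against the second over the list alone), the first call being lost without INK128 replicate 1 or doxorubicin replicate 2 (adjusted p 0.0517 to 0.0588) and without replicate 1 of every group (0.0628, range over alternatives 0.00112 to 0.0628). Over all genes 4146 were higher and 3853 lower with INK128 than with doxorubicin, and 4299 and 4000 than with palbociclib.

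The 3 responses of A549 were compared gene by gene. With doxorubicin and palbociclib 3812 genes were higher with both (n1×n2/N gives 974), 3565 lower with both (861) and 0 opposite. Pearson's r of the log2 fold changes across 19550 genes, which are not independent replicates, was 0.966 (covariance 1.4). Between doxorubicin and INK128 1876 genes were higher with both (899), 2078 lower with both (805) and 462 opposite, with r = 0.537 (covariance 0.612). Between palbociclib and INK128 the numbers were 1821 (892), 2005 (813) and 511, with r = 0.5 (covariance 0.594). All 3 responses shared their control libraries. In 20 simulations of unchanged groups against the same controls r averaged 0.494 and reached 0.509, with a covariance of 0.052. Shared controls alone thus gave an r near those of both INK128 pairs, so that r cannot tell whether their responses were shared. The covariances of both pairs were above the simulated one. In the simulations 0 genes on average were called higher with both and 0 lower with both. With single libraries left out r ran from 0.892 to 0.97, 0.383 to 0.62 and 0.361 to 0.581 for the 3 pairs in order. The last 2 were lowest without INK128 replicate 1. Shared calls were counted with all libraries alone. Of 3812 genes higher with both inducers, 1870 were lower with INK128 than with both and 1672 higher than in controls. Of 3565 lower with both, 1692 were higher with INK128 than with both. Choosing genes on these libraries favours such reversals, also in SK-MEL-147.

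**Figure D2:**
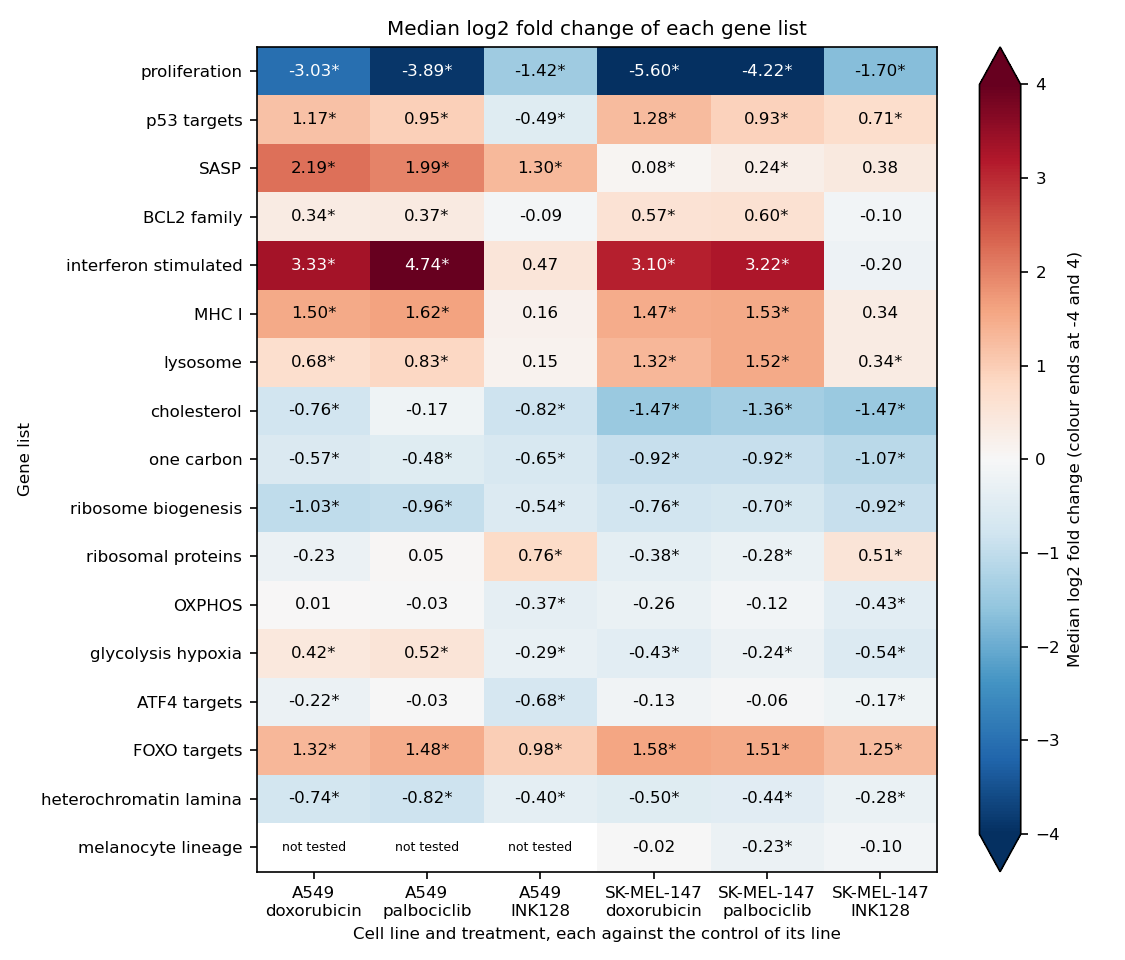
Median log2 fold change against control of each gene list (vertical axis) for each line and treatment (horizontal axis), printed and shown as colour, where an asterisk marks a fry adjusted p under 0.05. In A549 the interferon-stimulated genes stood at 3.33 with doxorubicin, 4.74 with palbociclib and 0.47 with INK128, and the ribosomal protein genes at -0.23, 0.05 and 0.76.

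In SK-MEL-147 doxorubicin left little expression of cycling genes. All 32 of 32 proliferation genes fell (median -5.6, adjusted p 1.42e-07). MKI67 stood at 0.754 ± 0.925 CPM against 545 ± 62.8 CPM (SD, n = 4 in each group of this line), a log2 fold change of -9.51 ± 1.36, adjusted p 1.41e-05. The mitotic kinesin gene KIF20A fell by 8.39 ± 0.88. Heterochromatin and lamina genes were lower in 14 of 26 cases and higher in 4 (median -0.5, adjusted p 8.2e-08). LMNB1 fell from 225 to 5.73 CPM (adjusted p 2.84e-08), and TMPO, which encodes a lamina-associated protein, fell by 4.82 ± 0.3, while the histone methyltransferase gene KMT5B rose by 0.65 ± 0.11. CDKN1A stood at 1937 ± 440 CPM against 354 ± 142 CPM (2.45 ± 0.29, adjusted p 1.84e-06). Targets of p53 rose in 21 of 25 cases and fell in 1 (median 1.28, adjusted p 1.72e-05). FOXO targets rose (15 of 19 higher, 1 lower, median 1.58, adjusted p 1.42e-07), and PIK3IP1 rose by 4.92 ± 0.29. The BCL2 family moved both ways (8 of 15 higher, 5 lower, median 0.57, adjusted p 2.86e-05). The pro-apoptotic BMF rose by 4.97 ± 0.33 and BCL2 fell by 2.73 ± 0.28, and BCL2A1 had no count with doxorubicin and was at least 9.89-fold lower than in controls. Without doxorubicin replicate 2, MKI67 was at -10.79.

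Interferon, antigen presentation and lysosomal genes rose with doxorubicin in SK-MEL-147. Interferon-stimulated genes were higher in 37 of 38 cases (median 3.1, adjusted p 0.00227), and IFI6 stood at 482 ± 413 CPM against 4.61 ± 1.75 CPM (6.7 ± 0.94, adjusted p 1.16e-05). Their sum ran from 1216 to 6086 CPM over the 4 doxorubicin replicates and from 437 to 638 CPM over the controls. MHC class I genes rose in 13 of 17 cases (median 1.47, adjusted p 0.000315), HLA-B to 1493 ± 655 CPM against 97.2 ± 43.5 CPM. Lysosomal genes rose (31 of 40 higher, 1 lower, median 1.32, adjusted p 2.79e-06), the acid glucosidase gene GAA by 4.11 ± 0.24 and the cathepsin gene CTSF by 3.55 ± 0.14. Of the secretory genes 12 of 29 were higher and 8 lower (12 and 9 over the list alone, median 0.08, adjusted p 0.00227). The growth factor binding gene IGFBP7 rose by 5.67 ± 0.27 and the decoy receptor gene TNFRSF11B fell by 2.72 ± 0.36. CXCL8 stood at 2.3 ± 2.03 CPM against 6.12 ± 3.91 CPM (adjusted p 0.0708). With only those 2 groups fitted, an alternative chosen after seeing the data, its adjusted p was 0.0489, and with replicates as blocks 0.00515 (range over alternatives 0.00515 to 0.272).

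Several lists fell in SK-MEL-147 with doxorubicin. Cholesterol genes fell in 20 of 22 cases (1 higher, median -1.47, adjusted p 8.03e-07). Genes of serine and one-carbon metabolism fell (1 of 25 higher, 19 lower, 1 and 20 over the list alone, median -0.92, adjusted p 1.42e-07), and PHGDH of serine synthesis fell by 3.27 ± 0.25. Ribosome biogenesis genes fell (0 of 30 higher, 27 lower, median -0.76, adjusted p 8.2e-08), and the fibrillarin gene FBL fell by 2.91 ± 0.22. Glycolysis and hypoxia genes fell on balance (6 of 26 higher, 14 lower, median -0.43, adjusted p 0.000315). LDHA fell by 1.67 ± 0.18, while the glucose transporter gene SLC2A1 rose by 1.26 ± 0.2. Ribosomal protein genes were lower in 29 of 53 cases (0 and 26 over the list alone, median -0.38, adjusted p 0.0206), with RPSA at -1.04 ± 0.15. ATF4 targets did not pass (7 of 24 higher, 9 lower, median -0.13, adjusted p 0.449, mean 0.12). Nor did the melanocyte lineage (1 of 9 higher, 2 lower, median -0.02, adjusted p 0.195, mean 0.12) or respiratory chain genes (6 of 36 higher, 16 lower, median -0.26, adjusted p 0.0927). MITF, the master transcription factor gene of melanocytes, fell by 0.64 ± 0.15. In all 5724 genes were higher and 5355 lower of 18516, 3309 and 2301 by more than 1 on the log2 scale. The ribosomal protein call was lost without control replicate 2 or doxorubicin replicate 2 or 4 (adjusted p 0.0561 to 0.0869). The respiratory chain list had adjusted p 0.0242 without control replicate 1 and 0.0384 with scaling by library size alone (range over alternatives 0.0242 to 0.347).

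Palbociclib in SK-MEL-147 was compared with no treatment in turn. All 32 of 32 proliferation genes fell (median -4.22, adjusted p 8.26e-08). E2F8 fell by 6.06 ± 0.41, and MKI67 stood at 14.2 ± 22.7 CPM against 545 ± 62.8 CPM. CDKN1A rose by 1.41 ± 0.28, adjusted p 0.000408, with p53 targets higher in 18 and lower in 1 of 25 cases (19 and 1 over the list alone, median 0.93, adjusted p 0.000551). Interferon-stimulated genes rose in 36 of 38 (37 and 0 over the list alone, median 3.22, adjusted p 0.00491), with sums from 1144 to 7359 CPM over replicates. BST2, which tethers viruses to the cell surface, had 1777 counts over the group against 3 in controls, a ratio of CPM of 707 (241 to 3430) (95% counting interval). MHC class I genes rose (14 of 17 higher, 0 lower, median 1.53, adjusted p 0.000286), B2M to 1952 ± 837 CPM against 518 ± 47.6 CPM. Lysosomal genes rose (31 of 40 higher, 1 lower, 32 and 1 over the list alone, median 1.52, adjusted p 9.03e-07), and GLB1 rose by 1.3 ± 0.23. FOXO targets rose (14 of 19 higher, 1 lower, median 1.51, adjusted p 5.85e-07), and TXNIP, which restrains glucose uptake, rose by 3.39 ± 0.2. Of the secretory genes 11 of 29 were higher and 5 lower (median 0.24, adjusted p 0.000118). IGFBP7 had 5.25 ± 0.26 and the growth factor gene FGF2 -2.22 ± 0.38. Without palbociclib replicate 2 the proliferation median was -4.83 and MKI67 had -7.48, and without replicate 1 the interferon median was 2.55.

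Cholesterol genes fell with palbociclib in SK-MEL-147 (1 of 22 higher, 20 lower, median -1.36, adjusted p 1.6e-06). Serine and one-carbon genes fell (1 of 25 higher, 19 lower, median -0.92, adjusted p 5.16e-07). Ribosome biogenesis genes fell (0 of 30 higher, 25 lower, 0 and 26 over the list alone, median -0.7, adjusted p 5.16e-07), and FBL fell by 2.7 ± 0.21. Heterochromatin and lamina genes fell on balance (3 of 26 higher, 12 lower, median -0.44, adjusted p 2.02e-07), and TMPO fell by 4.18 ± 0.29. The BCL2 family moved both ways (8 of 15 higher, 6 lower, 9 and 6 over the list alone, median 0.6, adjusted p 0.000149), with BMF at 4.72 ± 0.33 and BCL2 at -2.57 ± 0.28. Glycolysis and hypoxia genes fell on balance (5 of 26 higher, 11 lower, median -0.24, adjusted p 0.00491), and LDHA fell by 1.42 ± 0.18. Ribosomal protein genes were lower in 17 of 53 (0 and 16 over the list alone, median -0.28, adjusted p 0.0474). The melanocyte lineage passed (1 of 9 higher, 3 lower, median -0.23, adjusted p 0.0356, mean 0.14), and RAB38, a gene of pigment granules, fell by 2.12 ± 0.21. ATF4 targets (5 of 24 higher, 8 lower, median -0.06, adjusted p 0.117) and respiratory chain genes (5 of 36 higher, 10 lower, 5 and 8 over the list alone, median -0.12, adjusted p 0.253) did not pass. Over all genes 5494 were higher and 5318 lower, 3201 and 2105 by more than 1 on the log2 scale. The ribosomal protein call was lost without control replicate 2, 3 or 4 or palbociclib replicate 1, 2 or 4 (adjusted p 0.0798 to 0.147). That of the melanocyte lineage was lost without any one library other than control replicate 2 (0.0626 to 0.0951), and that of glycolysis and hypoxia genes without palbociclib replicate 4 (0.0856). ATF4 targets had adjusted p 0.0339 without control replicate 3. With replicates as blocks ATF4 targets had 0.0135 and ribosomal protein genes 0.0609 (ranges over alternatives 0.0135 to 0.433 and 0.0187 to 0.147).

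INK128 in SK-MEL-147 raised ribosomal protein genes and lowered some lists. Of the ribosomal protein genes 37 of 53 rose and 0 fell (median 0.51, adjusted p 0.00729). RPS18 rose from 1222 ± 136 to 2742 ± 706 CPM (1.17 ± 0.18, adjusted p 4.2e-05). Ribosome biogenesis genes fell (0 of 30 higher, 27 lower, 0 and 28 over the list alone, median -0.92, adjusted p 2.06e-07), and the dyskerin gene DKC1 fell by 1.25 ± 0.12. Cholesterol genes fell in 21 of 22 cases (1 higher, median -1.47, adjusted p 6.72e-07). Serine and one-carbon genes fell in 19 of 25 (1 higher, median -1.07, adjusted p 1.3e-06), PSAT1 from 161 to 20.5 CPM (adjusted p 2.31e-08). Glycolysis and hypoxia genes fell in 14 of 26 (4 higher, median -0.54, adjusted p 1.3e-06), and the hexokinase gene HK2 fell by 1.71 ± 0.12. Respiratory chain genes fell in 26 of 36 (2 higher, median -0.43, adjusted p 0.000242), and NDUFB3 fell by 0.97 ± 0.1. FOXO targets rose (14 of 19 higher, 0 lower, 16 and 0 over the list alone, median 1.25, adjusted p 1.37e-06), and FOXO1 itself rose by 3.59 ± 0.36. Lysosomal genes rose (19 of 40 higher, 3 lower, 18 and 3 over the list alone, median 0.34, adjusted p 0.0114), and GAA rose by 2.69 ± 0.23. BMF was among the 5 largest rises (4.99 ± 0.33), with the cell adhesion gene MDGA1 (5.97 ± 0.33) and the nuclear receptor gene NR4A2 (4.68 ± 0.43). ARG2, the mitochondrial arginase gene, was among the 5 largest falls (-3.05 ± 0.17).

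Cell cycle and p53 genes also moved with INK128 in SK-MEL-147. Proliferation genes fell in 30 of 32 cases (0 and 32 over the list alone, median -1.7, adjusted p 0.000254), and AURKA fell by 2.63 ± 0.27. MKI67 stood at 140.2 ± 8.44 CPM against 545 ± 62.8 CPM (-1.96 ± 0.92, adjusted p 0.0783). CDKN1A rose by 1.38 ± 0.28, adjusted p 0.000531, and p53 targets were higher in 15 and lower in 2 of 25 cases (median 0.71, adjusted p 0.00208). BBC3 rose by 1.75 ± 0.2 and the kinase gene PLK2 fell by 1.33 ± 0.19. Genes of heterochromatin and the lamina fell on balance (4 of 26 higher, 12 lower, median -0.28, adjusted p 8.6e-06). The lamin B receptor gene LBR fell by 2.11 ± 0.12 and KMT5B rose by 0.8 ± 0.11. Interferon-stimulated genes (4 of 38 higher, 0 lower, 3 and 0 over the list alone, median -0.2, adjusted p 0.903, mean -0.18) and MHC class I genes (7 of 17 higher, 3 lower, median 0.34, adjusted p 0.366) had no shift in common. HLA-B rose (1.43 ± 0.34, adjusted p 0.00194). Secretory genes were mixed (7 of 29 higher, 9 lower, median 0.38, adjusted p 0.141), with IL1B up from 10.6 to 146 CPM (adjusted p 8.61e-08). ATF4 targets passed with the fewer genes up (7 of 24 higher, 9 lower, median -0.17, adjusted p 0.034). The BCL2 family (4 of 15 higher, 3 lower, median -0.1, adjusted p 0.261, mean 0.37) and the melanocyte lineage (3 of 9 higher, 2 lower, median -0.1, adjusted p 0.809, mean 0.16) did not pass. The lineage factor gene SOX10 had 0.91 ± 0.17 and MITF -1.21 ± 0.16. In all 5521 genes were higher and 5352 lower, 2963 and 1790 by more than 1 on the log2 scale. With replicates as blocks (replicate block) the adjusted p was 0.0414 for MKI67, 0.0308 for GLB1 (-0.34 ± 0.23, adjusted p 0.206 without blocks, range over alternatives 0.0308 to 0.42), 0.0169 for secretory genes and 0.0486 for the BCL2 family (range over alternatives 0.0486 to 0.721). MKI67 had 2.28e-06 with only those 2 groups fitted (range over alternatives 2.28e-06 to 0.165). The ATF4 call was lost without control replicate 1, 2 or 4 or INK128 replicate 1, 3 or 4 (0.0635 to 0.163) and with scaling by library size alone (0.0843, range over alternatives 0.00396 to 0.163), and secretory genes had adjusted p 0.0135 without control replicate 1 (range over alternatives 0.0135 to 0.371).

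Set against the inducers, INK128 in SK-MEL-147 left cycling genes higher and interferon genes lower, with doxorubicin again given first. Proliferation genes were higher in 31 and 32 of 32 (medians 3.91 and 2.25, adjusted p 3.15e-05 and 9.59e-05). Heterochromatin and lamina genes were higher in 11 and 11 of 26 (2 and 2 lower, medians 0.21 and 0.13, adjusted p 7.64e-05 and 0.000616, 10 and 2 against the second over the list alone). LMNB1 had 3.51 ± 0.4, adjusted p 4.01e-06 against doxorubicin. HMGA1, an abundant chromatin gene, was at 1548 CPM with INK128 against 159 and 243. Ribosomal protein genes were higher in 52 and 50 of 53 (medians 0.93 and 0.88, adjusted p 0.000194 and 0.000383, 53 and 0 against the first over the list alone), RPL12 by 1.52 ± 0.22 and 1.58 ± 0.22. Interferon-stimulated genes were lower in 34 and 35 of 38 (medians -2.85 and -3.15, adjusted p 0.00479 and 0.00878, 0 and 35 against the first over the list alone). XAF1, a gene that favours apoptosis, had no count with INK128 and was at least 154-fold and 239-fold lower. MHC class I genes were lower in 14 and 15 of 17 (medians -1.45 and -1.42, adjusted p 0.00181 and 0.00178, 0 and 15 against the first over the list alone). Lysosomal genes were lower in 31 and 31 of 40 (2 and 2 higher, medians -0.98 and -1, adjusted p 0.000194 and 9.59e-05, 3 and 31 against the second over the list alone), with CTSB at -1.92 ± 0.16 against palbociclib. Ribosome biogenesis genes did not pass against doxorubicin (5 of 30 higher, 4 lower, median -0.01, adjusted p 0.502) and were lower on balance than with palbociclib (1 of 30 higher, 10 lower, median -0.2, adjusted p 0.0263). That call was lost without INK128 replicate 2 or palbociclib replicate 3 (adjusted p 0.0618 to 0.0639) and with scaling by library size alone (0.084, range over alternatives 0.00969 to 0.084). Glycolysis and hypoxia genes were lower in 9 and 13 of 26 (5 and 4 higher, medians -0.26 and -0.39, adjusted p 0.000594 and 9.59e-05). The survival gene BCL2 was higher than with either inducer (2.18 ± 0.28 and 2.01 ± 0.28). Over all genes 4588 were higher and 4436 lower with INK128 than with doxorubicin, and 4960 and 4785 than with palbociclib. Against palbociclib, the proliferation median was 3.02 without its replicate 2 and the interferon median -2.44 without its replicate 1.

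In SK-MEL-147 with doxorubicin and palbociclib 4896 genes were higher in both (n1×n2/N gives 1698), 4660 lower in both (1538) and 2 opposite, with r = 0.953 across 18516 genes (covariance 1.64). For doxorubicin and INK128 the numbers were 3416 (1707), 3638 (1548) and 545, with r = 0.633 (covariance 0.901). For palbociclib and INK128 they were 3071 (1638), 3406 (1537) and 777, with r = 0.579 (covariance 0.765). Unchanged groups simulated against the shared controls gave r = 0.493 on average and 0.517 at most in 20 simulations, with a covariance of 0.038. With the 4 controls split so that each treatment had 2 of its own, r was 0.84 to 0.897 for the inducers. It was 0.499 to 0.594 for doxorubicin and INK128 and 0.429 to 0.54 for palbociclib and INK128. With single libraries left out r ran from 0.936 to 0.955, 0.612 to 0.668 and 0.551 to 0.618 for the 3 pairs in the order given. Of 4896 genes higher with both inducers, 2290 were lower with INK128 than with both and 2924 higher than in controls. Of 4660 lower with both, 1878 were higher with INK128 than with both.

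The lines were compared treatment by treatment, with no library shared between them; the doses of palbociclib and INK128 differed. Across 16726 genes tested in both lines, 2282 were higher (1018 from n1×n2/N) and 2748 lower (1172) in both with doxorubicin, with r = 0.631. Palbociclib gave 2228 (977), 2703 (1179) and r = 0.637, and INK128 2217 (979), 2559 (1070) and r = 0.583. Opposite calls numbered 406, 403 and 284.

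The difference between the lines was tested as an interaction, SK-MEL-147 less A549. With INK128, p53 targets differed by a median of 1.14 (adjusted p 0.000984) on the log2 scale. Of these, 13 of 25 were more positive in SK-MEL-147 and 1 more negative (18 and 1 over the list alone), and CDKN1A differed by 1.92 ± 0.43, adjusted p 0.00399. ATF4 targets differed by 0.37 (adjusted p 0.000984) and ribosome biogenesis genes by -0.28 (adjusted p 0.00804). KMT5B (0.74 ± 0.17, adjusted p 0.00587) and BCL2L1 (0.61 ± 0.16, adjusted p 0.0147) were more positive in SK-MEL-147. With doxorubicin, proliferation genes were lower in SK-MEL-147 (24 of 32, median -2.28, adjusted p 0.00275), as was the secretory list (-1.88, adjusted p 0.00275). CXCL8 differed by -6.84 ± 1.05, adjusted p 4.44e-05. Serine and one-carbon (-0.62, adjusted p 0.000139), cholesterol (-0.68, adjusted p 0.00123) and glycolysis and hypoxia genes (-0.62, adjusted p 1.99e-05) were also lower, while lysosomal genes were higher (0.56, adjusted p 0.00313). With palbociclib, cholesterol genes (-0.97, adjusted p 0.000115) and glycolysis and hypoxia genes (-0.42, adjusted p 0.000115) were again lower in SK-MEL-147 and CXCL8 differed by -5.68 ± 1.01, adjusted p 0.000274. No difference passed for interferon-stimulated genes (medians 0.29, -0.53 and -0.37, adjusted p 0.956, 0.513 and 0.636 for doxorubicin, palbociclib and INK128). Nor did any for MHC class I genes (medians 0.28, 0.18 and 0.35, adjusted p 0.584, 0.841 and 0.744) or ribosomal protein genes (medians -0.36, -0.59 and -0.19, adjusted p 0.36, 0.0509 and 0.425). Of 21761 genes tested, 1848 were more positive and 2455 more negative in SK-MEL-147 with doxorubicin, 1822 and 2350 with palbociclib and 1417 and 1180 with INK128. Lysosomal (0.6, adjusted p 0.0283), serine and one-carbon (-0.37, adjusted p 0.00175), ATF4 target (-0.34, adjusted p 0.0133) and FOXO target genes (-0.25, adjusted p 0.0365) also differed with palbociclib. Each of these 4 calls was lost without 1 or more of the 14 libraries (adjusted p of the lost calls 0.0642 to 0.0859, 0.0686 to 0.0834, 0.059 to 0.432 and 0.0674 to 0.416 in that order, ranges over alternatives 0.00268 to 0.127, 0.000735 to 0.0834, 0.00268 to 0.432 and 0.00798 to 0.467). The last 3 were lost with scaling by library size alone as well, at medians of -0.18, -0.13 and -0.06 (adjusted p 0.0674, 0.254 and 0.246). With both A549 libraries numbered 2 kept apart, ATF4 and FOXO targets had medians of -0.07 and -0.03 (adjusted p 0.387 and 0.467). Without replicate 1 of every A549 group the lysosomal, ATF4 and FOXO calls were lost (0.127, 0.0752 and 0.127), and the FOXO call with RLE factors (0.0726). Ribosomal protein genes passed with palbociclib without replicate 3 of either line's palbociclib group (0.0206 to 0.0329) and with replicates as blocks (0.0401, range over alternatives 0.0206 to 0.319). The INK128 call of ribosome biogenesis genes was lost without SK-MEL-147 control replicate 2 (0.0629) and with scaling by library size alone (0.0925, range over alternatives 0.00581 to 0.0925). That of secretory genes with doxorubicin was lost with both A549 libraries numbered 2 kept apart (0.0509, range over alternatives 1.8e-06 to 0.0509).

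**Figure D3:**
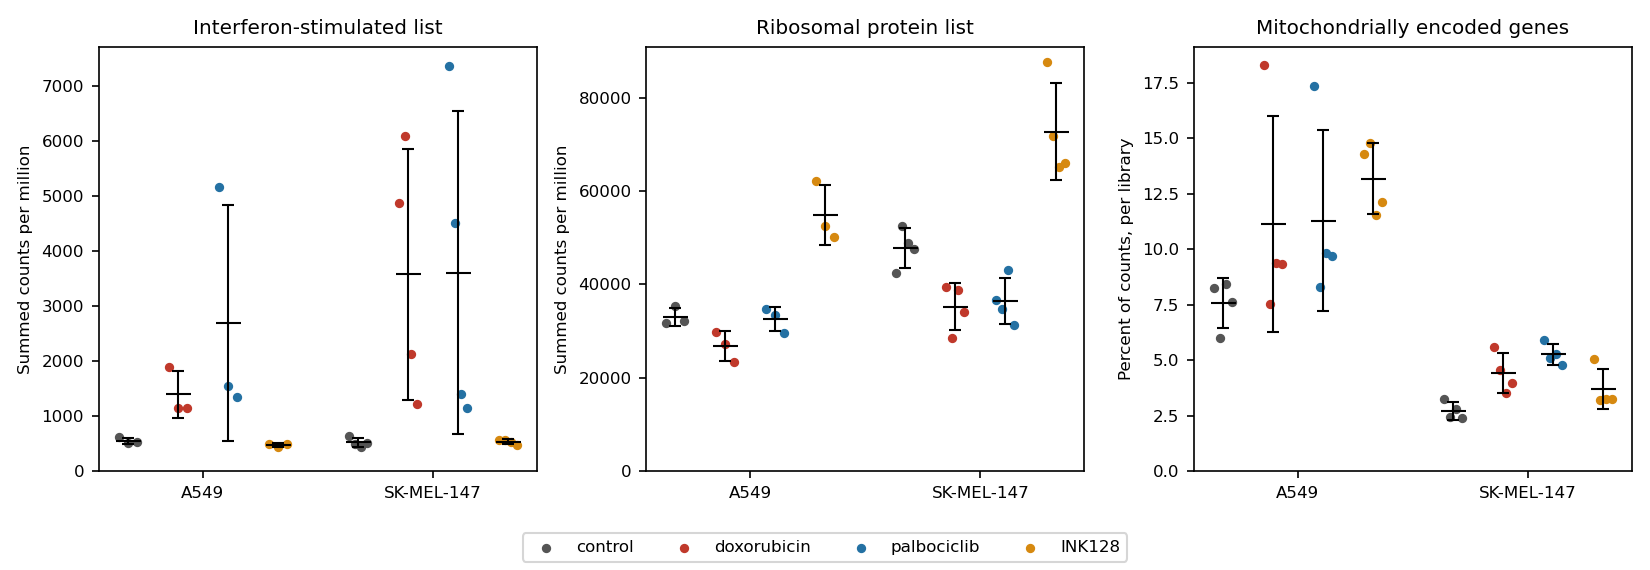
Summed counts-per-million of the interferon-stimulated and ribosomal protein genes in each replicate (n = 3 in A549, n = 4 in SK-MEL-147), and the percentage of counts from the mitochondrial genome in each of 4 libraries per group, by line and treatment (colour), with means and SD in black. The interferon sum reached 5166 CPM in A549 palbociclib replicate 1 and ran from 1353 to 1555 CPM in the other 2.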

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

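The tests of other mRNAs with a 5' pyrimidine tract, of another melanoma line and of the dose, and the regrouping of the A549 doxorubicin and control samples, were chosen after the results were seen.

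In 7 of 64 groups of 4 tested, 1 sample lay far from the other 3, where chance gives about 1 in 20 groups of independent samples. A549 groups had 4 only in the tests of totals and mitochondrial shares, with both libraries numbered 2 taken apart, which the labels do not give as independent. The mitochondrial genome gave 17.335% of counts in A549 palbociclib replicate 1 (95% Wilson interval 17.32 to 17.35%) against 8.296 to 9.808%, and 5.056% in SK-MEL-147 INK128 replicate 1 (5.049 to 5.064%) against 3.192 to 3.268%. The other 5 were panel genes in SK-MEL-147. With palbociclib, CDKN1A was at 1412 CPM in replicate 4 (others 737.1 to 806.1) and GDF15 at 2.383 CPM in replicate 2 (others 0.2504 to 0.574). With INK128, LMNB1 was at 50.18 CPM in replicate 2 (others 70.2 to 70.76), B2M at 492.2 CPM in replicate 4 (others 564.2 to 578.2) and SHMT2 at 105.6 CPM in replicate 3 (others 91.13 to 92.67).

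Responses that differed between the lines in the interaction test are given as SK-MEL-147 less A549, on the log2 scale, with a list's value being its median. With doxorubicin the lists were proliferation (-2.28), secretory genes (-1.88), lysosome (0.56), cholesterol (-0.68), serine and one-carbon metabolism (-0.62) and glycolysis and hypoxia (-0.62). Panel genes were LMNB1 (-2.63), MKI67 (-5.89), IL6 (-3.77), CXCL8 (-6.84), BCL2L1 (0.48), KMT5B (0.81) and SHMT2 (-0.8). With palbociclib the lists were lysosome (0.6), cholesterol (-0.97), serine and one-carbon metabolism (-0.37), ATF4 targets (-0.34), FOXO targets (-0.25) and glycolysis and hypoxia (-0.42), and the genes IL6 (-3.99), CXCL8 (-5.68), KMT5C (0.79) and SHMT2 (-0.57). With INK128 the lists were p53 targets (1.14), ATF4 targets (0.37) and ribosome biogenesis (-0.28), and the genes CDKN1A (1.92), GLB1 (-0.99), BCL2L1 (0.61) and KMT5B (0.74). Adjusted p-values of all these lay under 0.05.

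Ribosomal protein genes were higher with INK128 in both lines, with medians of 0.76 in A549 and 0.51 in SK-MEL-147. Scaling of abundant genes was argued against, since 10000 lists matched on mean CPM had medians of -0.21 (95% of lists -0.44 to 0.01) and -0.03 (95% of lists -0.26 to 0.24), at least 0.55 lower, and so was a gain of short transcripts, since lists matched on length as well had -0.23 (95% of lists -0.44 to -0.01) and -0.03 (95% of lists -0.31 to 0.22), again at least 0.55 lower. Reads shared with pseudogenes were argued against too: members with at most 5 named pseudogenes had medians of 0.69 and 0.51 (at least 0.51), and those with 10 or more 0.76 and 0.43, although the mean share of counts on pseudogenes was higher with INK128 as given above. Translation of mRNAs with a 5' terminal oligopyrimidine tract depends on mTOR, and 21 other mRNAs of that kind had medians of 0.61 in A549 (11 higher, 0 lower, fry p 0.000126 before adjustment) and 0.22 in SK-MEL-147 (5 higher, 2 lower, fry p 0.0894). A response of that class as a whole may therefore underlie the pattern but stays open as a hypothesis, since the second p missed 0.05.

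Interferon-stimulated genes were higher with both inducers than with INK128 in both lines, and some libraries stood apart in their sums. That 1 library decides this was argued against, since the adjusted p of the list was at most 0.0372 over the 4 comparisons with any one library, or A549 replicate 1 of every group, left out, although the medians moved as given above. Scaling was argued against as well, with an adjusted p of at most 0.0134 with RLE factors or library size alone. The drugs' effects in each line remain the biological explanation, as a hypothesis found and tested on the same libraries.

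Targets of p53 were lower with INK128 in A549 and higher in SK-MEL-147, with the difference between lines at 1.14. Scaling was argued against (adjusted p at most 0.00161 with RLE factors or library size alone), and so was a single library (at most 0.00492 with each of 14 left out, 0 medians turned, A549 -0.754 to -0.403, SK-MEL-147 0.545 to 1.07). The series description names another melanoma line for INK128. Of all genes, 0 were under 0.1 CPM in every SK-MEL-147 INK128 library and at 2 CPM or more in every other SK-MEL-147 library (0 for A549 INK128 within A549, 2 and 226 between the 2 lines), but no other melanoma line was measured, so the number it would give is unknown and this cannot be told apart. The dose was 200 nM in A549 and 100 nM in SK-MEL-147, so that dose and line cannot be told apart, and a difference between the lines in the response to mTOR inhibition remains a hypothesis.

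Genes called by edgeR were also counted with the samples of the groups compared, fitted alone, split in other ways. In A549 there were 10 splits, too few for a share under 0.05. The real split gave 7723 genes for doxorubicin, 7984 for palbociclib and 8987 for INK128 against control, and 6693 and 7092 for INK128 against doxorubicin and palbociclib. The highest other gave 0 each time, with 639, 722, 565, 1059 and 1243 genes at an unadjusted p under 0.05 in the same order. In SK-MEL-147 only the real one of 35 splits gave as many genes, the lowest share possible. The real split and the highest other gave 10735 and 4 with doxorubicin, 10530 and 8 with palbociclib and 8759 and 8 for INK128 against palbociclib. Pairing, and so chance, was not excluded in these 3. Replicate numbers paired the samples in INK128 against control (10445 and 11) and doxorubicin (7923 and 2). There only 7 others part every pair, too few for a share under 0.05. These 7 gave 0 genes at most with edgeR, where no other split gave over 2676 and 2104 at an unadjusted p under 0.05. For the differences between the lines, 4, 3 and 4 of 100 splits drawn gave as many genes as the real one with doxorubicin, palbociclib and INK128. The real split and the highest other gave 4268 and 6756, 4186 and 6563 and 2883 and 6423 in that order. Splitting a line across its treatment adds that effect to the spread, and each of the others as large left 1 line whole. These counts do not test whether the lines differ.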

How the results depend on the processing

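Leaving replicate 1 out of every A549 group, leaving out mitochondrially encoded genes, and fitting only the groups compared for named genes were tests chosen after seeing the data. Of results with a call in an alternative, 1 had a fry direction opposite to the full fit's: ribosome biogenesis genes in the difference between lines with doxorubicin passed with fry's direction up without SK-MEL-147 control replicate 2 (median 0.32, adjusted p 0.0274, range over alternatives 0.0274 to 0.987), where the full fit had down (median 0.11, adjusted p 0.956). Medians of other lists also crossed 0, such as secretory genes with INK128 against palbociclib in SK-MEL-147 (-0.34 to 0.37 without palbociclib replicate 1) and serine and one-carbon genes with INK128 against palbociclib in A549 (-0.02 to 0.04 with library size only). Over single libraries left out the ribosome biogenesis median ran from 0.002 to 0.32. Within the lines, no count of genes higher or lower moved by over 1.5 times under any alternative, single libraries left out included. Differences between the lines moved further, and the cause was not tested. With library size only, 1521 genes were lower with palbociclib. With the replicate block, 2779 were higher with doxorubicin, 2781 higher and 3578 lower with palbociclib, and 2400 higher and 2345 lower with INK128. With both A549 libraries numbered 2 kept apart, 3048 and 3054 were higher with doxorubicin and palbociclib. With only the library titled 2, 1358, 1157 and 684 were lower with doxorubicin, palbociclib and INK128. Leaving out one library gave 1510 to 2813 higher and 1578 to 2379 lower with doxorubicin, 1500 to 2799 and 1350 to 2468 with palbociclib, and 764 to 1409 lower with INK128.

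Of calls on named genes, 639 of 639 kept their side of the threshold with RLE size factors, 635 of 639 with library size only, 627 of 629 with DESeq2, 4329 of 4514 with one library left out, 617 of 624 with only the groups compared, 290 of 299 without A549 replicate 1 and 636 of 639 with the block. Of calls on lists these numbers were 210 of 213 with RLE factors, 199 of 213 with library size only, 1706 of 1832 with one library left out, 120 of 128 with the libraries numbered 2 kept apart, 119 of 128 without A549 replicate 1 and 202 of 213 with the block. The median log2 value over all genes moved by more than 0.1 with library size only in 2 differences between the lines, from -0.103 to 0.061 with doxorubicin and from -0.1 to 0.09 with palbociclib. Where SK-MEL-147 missed the pairing rule, blocks gave 6281 genes higher and 6002 lower with doxorubicin (lowest correlation 0.041, 1 of 4 nearest their number). They gave 6088 and 5954 with palbociclib (0.074, 3 of 4) and 5653 and 5461 with INK128 against palbociclib (0.035, 4 of 4). The block gave an adjusted p of 0.007 (0.0563 unblocked, 0.00267 to 0.321 over alternatives) for serine and one-carbon genes with INK128 against doxorubicin in A549 and 0.053 (0.0279 unblocked, 0.0269 to 0.0758 over alternatives) for p53 targets in SK-MEL-147. Between the lines it gave 0.00155 (0.0815 unblocked, 0.00155 to 0.248 over alternatives) for secretory and 0.0233 (0.138 unblocked, 0.0233 to 0.375 over alternatives) for cholesterol genes with INK128 and 0.000108 (0.0509 unblocked, 0.000108 to 0.403 over alternatives) for secretory genes with palbociclib. Beyond these and the values given in the report, the block changed no other call. Depth limits weak genes: filterByExpr kept 19550 genes in A549 and 18516 in SK-MEL-147.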

Other observations

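The gene families and genes in this part were chosen after the data were seen, as were their tests. Values stand in the order doxorubicin, palbociclib and INK128. Collagen genes, which encode fibres of the matrix around cells, were higher in all 6 comparisons with control, in A549 (17, 14 and 14 of 31 higher, 1, 0 and 3 lower, medians 1.26, 1.14 and 1.11, adjusted p 0.000389, 0.00147 and 0.00349) and in SK-MEL-147 (14, 14 and 11 of 25 higher, 3, 3 and 3 lower, medians 2.08, 2.35 and 0.75, adjusted p 3.15e-05, 7.92e-06 and 0.00992). FN1, which encodes the matrix protein fibronectin, stood at 313 ± 49.8 CPM in A549 controls, 3610 ± 1770 with doxorubicin, 2920 ± 1470 with palbociclib and 1090 ± 806 with INK128 (3.53 ± 0.64, adjusted p 0.00106, 3.22 ± 0.63, adjusted p 0.00174, and 1.8 ± 0.6, adjusted p 0.0329). In SK-MEL-147 it rose with both inducers (adjusted p 9.17e-06 and 1.23e-06) and did not pass with INK128 (adjusted p 0.13). SPARC, which encodes another matrix protein, went from 941 ± 87.3 CPM in SK-MEL-147 controls to 4160 ± 765 with doxorubicin and 4610 ± 1200 with palbociclib (adjusted p 4.46e-07 and 2.9e-07), and had 955 ± 269 with INK128 (adjusted p 0.94). In A549 it rose with all 3 drugs (adjusted p 0.000314 and 0.00056 with the inducers and 0.0167 with INK128). Tubulin genes, of the microtubules, were lower in all 6 comparisons, in A549 (22, 24 and 23 of 32 lower, 0, 0 and 1 higher, medians -1.19, -1.39 and -0.97, adjusted p 0.000289, 0.000107 and 0.00101) and in SK-MEL-147 (24, 23 and 28 of 34 lower, 3, 2 and 3 higher, medians -1.32, -1.16 and -1.04, adjusted p 1.68e-07, 1.29e-06 and 1.75e-06).

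Genes of protein folding and breakdown were also lower with each drug in both lines. Proteasome subunit genes fell in A549 (12, 15 and 28 of 37 lower, 2, 2 and 0 higher, medians -0.3, -0.38 and -0.69, adjusted p 0.0234, 0.0127 and 0.000336) and in SK-MEL-147 (21, 22 and 30 of 37 lower, 4, 4 and 0 higher, medians -0.33, -0.33 and -0.59, adjusted p 0.000594, 0.00177 and 5.88e-06). Chaperonin and heat shock genes fell in A549 (45, 47 and 58 of 112 lower, 17, 12 and 7 higher, medians -0.38, -0.36 and -0.56, adjusted p 0.000289, 0.000107 and 4.33e-06) and in SK-MEL-147 (57, 54 and 72 of 108 lower, 20, 18 and 16 higher, medians -0.45, -0.41 and -0.74, adjusted p 3.15e-05, 0.000203 and 9.63e-07). Genes of the mitochondrial ribosome fell in A549 (30, 29 and 44 of 73 lower, 0, 0 and 0 higher, medians -0.42, -0.41 and -0.6, adjusted p 0.0185, 0.017 and 0.00349) and in SK-MEL-147 (44, 45 and 54 of 74 lower, 5, 5 and 2 higher, medians -0.49, -0.44 and -0.62, adjusted p 0.000259, 0.000506 and 1.3e-05). In A549 the proteasome and mitochondrial ribosome calls of both inducers were lost without some single libraries (adjusted p 0.0542 to 0.102, 0.00199 to 0.102 over all their alternatives). With INK128 NEAT1, the RNA scaffold of nuclear paraspeckles, went from 329 ± 64.8 to 1270 ± 238 CPM in A549 (1.95 ± 0.43, adjusted p 0.00455) and from 111 ± 53.5 to 690 ± 159 CPM in SK-MEL-147 (2.64 ± 0.44, adjusted p 9.82e-05). MALAT1, another long nuclear RNA, rose in A549 (1.88 ± 0.27, adjusted p 0.000446) and in SK-MEL-147 (2.4 ± 0.33, adjusted p 1.28e-05). In SK-MEL-147 both also rose with doxorubicin (1.61 ± 0.43, adjusted p 0.00381, and 1.77 ± 0.32, adjusted p 0.000142) and palbociclib (1.4 ± 0.42, adjusted p 0.0094, and 1.03 ± 0.31, adjusted p 0.00935). The mean share of counts on nuclear protein-coding genes was lower with INK128, as given above. In A549 keratin genes, of the epithelial cytoskeleton, were lower with INK128 (0 of 17 higher, 11 lower, median -1.23, adjusted p 0.00108) and did not pass with the inducers (adjusted p 0.507 and 0.569). Other than the calls named as lost, each family call given here was also found, in its direction, with RLE factors, with library size only and with each library of the comparison left out. The fry tests were adjusted over 9 families, and n was 3 per group in A549 and 4 in SK-MEL-147.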
